A study of Sus scrofa with 5 samples.

How the data were processed

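Single-cell RNA-seq was measured in 5 libraries of a pig embryonic stem cell line derived from embryos fertilized in vitro. Per the labels, 1 library came from undifferentiated cells and 4 from cells driven toward muscle for 8, 12, 20 or 25 days, prepared with the 10x Genomics 3' kit. Each group therefore held 1 library. No replicates were available, no test across libraries was possible, and no p-value is given.

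The deposited matrices hold counts, as whole numbers of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. Per the submitters' processing notes, Cell Ranger 7.0.1, R 4.3.3 and Seurat 4.3.0 were used. Per the file headers, the matrix format names Cell Ranger 4. The genome build and annotation were not given in the sources used here. Every library listed the same 22040 features, of which 15681 had a symbol in the file. A further 201 were named from a table of gene identifiers, and 6158 kept an identifier only. A symbol shared by several features applied to 12 features. Genes of the fixed lists without a matching symbol, among them POU5F1, TTN, MKI67 and IGF2, were not analysed here. MYLPF was not matched in the lists, and the feature MYL11 was kept outside them.

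The deposited files held all barcodes, between 2615494 in the undifferentiated library and 3009731 at day 20. The labels give 21361 cells for the undifferentiated library, 23029 for day 8, 26231 for day 12, 23324 for day 20 and 19394 for day 25. In each library that number of barcodes with the most UMIs was taken as cells, which gave median UMI counts per cell of 4477, 9628, 8361, 6203.5 and 7904 in the same order. The labels state 4477, 9628, 8361, 6204 and 7904. Cells with fewer than 500 genes or over 20% mitochondrial UMIs were left out. Doublets were called with Scrublet as built into scanpy 1.11.5, at an expected rate of 0.8% per 1000 cells and the automatic threshold. It called 9.05%, 12.5%, 13.1%, 9.86% and 8.79% of the cells that passed the filter in the undifferentiated, day 8, day 12, day 20 and day 25 libraries, and these cells were left out. Of 113339 called cells, 111246 passed the filter and 99207 were retained.

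For each library, UMIs were summed over its retained cells and divided by the library total, and the ratio is given in CPM (parts per 10 to the power of 6). Library totals ranged from 109805839 to 185908280 UMIs. For each of 5 comparisons, a gene was measured at 10 CPM or more in the higher library and counted as apart at a ratio of 2 or more. A library with fewer than 3 UMIs of a gene was set to 3 UMIs for the ratio, which makes that ratio a bound. Levels carry exact Poisson intervals, ratios and shares exact binomial (Clopper-Pearson) intervals, at 95% confidence. All intervals cover counting error only, not the variation between cultures.

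The genes named in the text follow a fixed rule. Per comparison, they are the 10 highest and 10 lowest ratios among genes with a symbol at 50 CPM or more, leaving out mitochondrial and ribosomal protein genes. To these come up to 4 members of each list with the largest ratios, a fixed set of regulators and muscle genes, and the top 10 genes of each cluster. Some genes under this rule are not reported. Genes named outside this rule are said to have been chosen after their values were seen. Gene lists numbered 36, of which 20 were cell type markers. A list needed 4 measured members, and its median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below the percentile 2.5 or above 97.5. That percentile describes these libraries and is not a p-value.

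The ratio step was tested on simulated counts with 200 genes altered, 100 of them by 3-fold and the others by 1.5-fold. Both libraries of a pair were drawn with Poisson error from the profile of the second library. No variation between cultures was simulated, so the result checks the code and gives no error rate for the real comparisons. For day 8 against undifferentiated (9131 genes), day 12 against day 8 (9004), day 20 against day 12 (9531), day 25 against day 20 (9276) and day 25 against undifferentiated (9133), 100% of the 3-fold genes and 0% of the 1.5-fold and unaltered genes passed the ratio of 2. The intervals covered the true ratio in 95.13%, 95.11%, 95.31%, 95.02% and 95.16% of genes in that order.

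Shares of cells with 3 or more genes of a list were taken after each cell was thinned to 2000 UMIs, since median depth differed between libraries. Cells under that depth were left out, which were 5176 in the undifferentiated library, 2284 at day 8, 2623 at day 12, 2897 at day 20 and 2305 at day 25. The background was the same share in 20000 simulated droplets drawn from the free RNA of each library, taken as the barcodes with 1 to 100 UMIs. Free RNA gives UMIs of a gene in cells that do not express it. For the share of called doublets with PAX7 and SOX2, single draws differed, so the chance of finding both genes was summed exactly over all draws, a choice made after results of single draws were seen.

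All retained cells were clustered together without integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden with igraph 0.11.9, resolution 1), which gave 27 clusters. A class name ending in "-like" was given where at least 3 markers of 1 fixed list were 2-fold higher at 20 CPM or more, more than for any other class. At least 1 of these markers had to lie among the top 10 genes by fold, with no other class holding more of them there. For clusters whose median UMI count was under 1/3 of that of their library, the class had to hold more of them there than any other. Clusters mostly from 1 library may reflect that library and not a cell type.

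The comparisons, filters, lists, markers, naming of genes and alternatives were fixed before the data were examined. The scoring rule for cluster names, the further clustering of clusters 19 and 20 (20 components, resolution 0.5, 9 sub-clusters), the exclusion of clusters from the sums and a list of 42 interferon-stimulated genes were chosen after seeing the data. Alternatives were all barcodes with 1000 or more UMIs, other cell filters, doublets kept, equal weight per cell, TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, filters at 1 and 50 CPM, and subtraction of 10% of each library as free RNA. For shares and clusters they were 1000 UMIs per cell, 2 or 5 genes in place of 3, resolutions of 0.5 and 2, and 50 components. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3. A comparison within skeletal muscle-like cells was planned and was not possible, because no cluster was named so. Barcodes outside the called cells entered no comparison except as the free RNA profile and, at day 12, in the alternative of all barcodes with 1000 or more UMIs.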

Results

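Directed myogenic differentiation of pig embryonic stem cells was followed by single-cell RNA-seq in 5 libraries, and the series asks how skeletal muscle development proceeds in culture. Per the labels, the undifferentiated cells grew with FGF2, activin A, the GSK3 inhibitor CHIR99021 and the tankyrase inhibitor IWR-1. Differentiation began with CHIR99021 and the BMP receptor inhibitor LDN193189, and FGF2 was added later. HGF, IGF1, FGF2 and LDN193189 were present up to day 8, IGF1 alone up to day 12, and IGF1 with HGF up to day 25. After filtering, 18733 cells of the undifferentiated library, 19910 at day 8, 22726 at day 12, 20624 at day 20 and 17214 at day 25 were retained. Their median depths were 4396, 9244.5, 7882.5, 5966.5 and 7674.5 UMIs per cell in that order. Viability before loading was 83.8%, 83.1%, 93.0%, 82.7% and 82.4%. The retained cells held 752833029 UMIs, and levels below are parts of a library's retained total, in CPM, with intervals for counting error only.

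Skeletal muscle regulators were at their highest at day 25 in these libraries, at low levels in the whole culture. MYOD1, a transcription factor that commits cells to muscle, lay between 0.0328 and 0.0861 CPM up to day 12. It stood at 0.869 (95% interval 0.717 to 1.04) at day 20 and 2.57 (2.32 to 2.85) at day 25. MYOG, which drives terminal differentiation, stood at 1.23 CPM (1.06 to 1.43) at day 25 and at 0.0914 or less in every earlier library. It had 0 UMIs before differentiation (upper 95% limit 0.0336 CPM). MYMK, needed for myoblast fusion, stood at 6.07 CPM (5.67 to 6.48) at day 25 against 0.272 at day 20. The embryonic myosin MYH3 stood at 8.80 (8.32 to 9.30) against 0.725, and the perinatal myosin MYH8 at 3.60 (3.29 to 3.92) against 0.378. MYF5 stood at 0.846 CPM (0.702 to 1.01) at day 25 and 0.325 at day 20. The skeletal actin ACTA1 did not follow them in the whole culture, with 13.5 CPM before differentiation and 4.24 at day 25. It was still among the markers at least 2-fold higher in sub-cluster 8, described below, than in all other cells. ACTC1, the actin of early muscle, stood at 17.5, 2.80, 9.91, 27.7 and 121 CPM in the order of the libraries, and the intermediate filament gene DES at 0.865, 1.77, 1.07, 3.76 and 24.2.

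The upstream regulators had another course. PAX3, a regulator of dermomyotome and dorsal neural tube, stood at 8.35 CPM before differentiation and at 45.2, 70.6, 38.2 and 36.6 at days 8, 12, 20 and 25. PAX7, which marks muscle progenitors and dorsal neural cells, stood at 19.8, 13.6, 34.8, 10.3 and 18.0. TBXT, the mesoderm regulator brachyury, stood at 0.638, 0.634, 0.409 and 0.0453 CPM up to day 20, with 1 UMI at day 25. MSGN1, a presomitic regulator, had 0 UMIs in all 5 libraries, which allows at most 0.0273 CPM. TBX6 lay between 1.00 and 3.03 CPM, and the somite gene MEOX1 between 0.237 and 2.17. NANOG stood at 22.7 CPM (21.8 to 23.6) before differentiation and at 0.186 or less afterwards, while SOX2, shared by stem and neural cells, stood at 109, 174, 193, 54.1 and 58.3. The collagen gene COL1A1 stood at 31.6, 34.6, 124, 166 and 229 CPM, and the neuronal tubulin TUBB3 at 189, 13.3, 75.5, 39.2 and 121. Before differentiation, 55.8% of COL1A1 UMIs lay in cluster 4, which is described below. SOX10, a neural crest regulator, stayed between 0.2004 and 1.2 CPM.

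**Figure D1:**
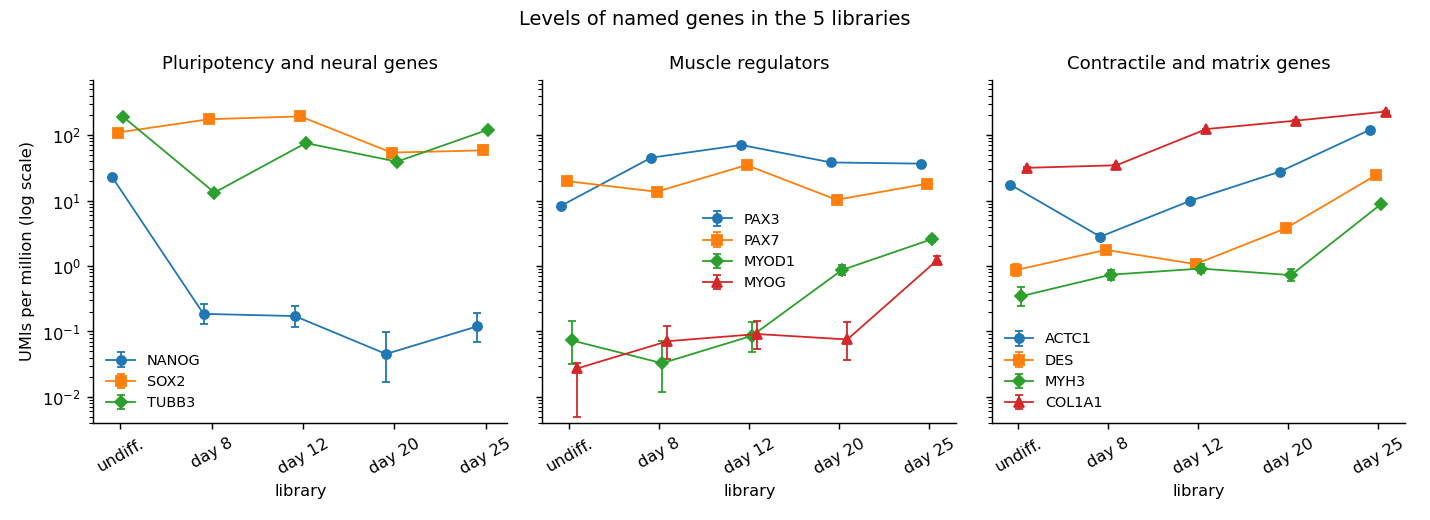
Levels of 11 named genes in the 5 libraries, as CPM on a log axis, with bars for 95% counting intervals. MYOG had 0 UMIs before differentiation, and its point there is drawn at the level of 3 UMIs (0.0273 CPM). NANOG lies at 22.7 before differentiation and at 0.186 or less afterwards, while MYOD1, MYOG, MYH3, DES and ACTC1 lie highest at day 25.

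The comparison of day 8 with undifferentiated cells asks what the first phase of induction left in the culture. Most measured pluripotency genes were lower at day 8. DNMT3B, a DNA methyltransferase of early embryonic cells, stood at 5.94 against 454 CPM, a log2 ratio of -6.26 (95% interval -6.34 to -6.17). The Nodal antagonist LEFTY2 had a log2 ratio of -6.86, NANOG -6.93 and PRDM14, a repressor of differentiation, -6.73. HOX genes, which set position along the body axis, were far higher. HOXA9 stood at 55.8 against 0.565 CPM (6.63, 6.27 to 7.01) and HOXB9 at 120 against 1.59 (6.24, 6.02 to 6.46).

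Of 9903 genes measured, 1178 were at least 2-fold higher at day 8 and 1449 at least 2-fold lower, so that 44.8% of the genes apart were higher. The balance turned with the scaling, with 1438 higher and 1250 lower (53.5%) under TMM factors and 1331 and 1343 (49.8%) under DESeq2 size factors. Among the genes with the largest ratios, ANKRD1, a nuclear ankyrin repeat protein of muscle and stretched cells, had a log2 ratio of 5.97. The glycolytic enzyme gene ENO2 had 5.64, the thioredoxin inhibitor TXNIP 5.62, the chemokine CXCL14 5.53, the link protein HAPLN1 4.64, the integrin ITGA8 4.61, the homeobox gene IRX3 4.43 and the adaptor SKAP1 4.06. On the lower side, the cytokine TNFSF11 had -7.71 (0.443 against 92.5 CPM) and ERAS, a Ras gene of embryonic stem cells, -6.79. TLL2 had -5.95, TMEM132D -5.94, the transcription factor BCL11A -5.86, BRINP1 -5.75 and the kinase gene DGKB -5.67.

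By list, 6 of 9 measured pluripotent stem cell genes were at least 2-fold lower at day 8 and 0 higher (median log2 ratio -4.60). All 5 anterior HOX genes (median 5.32) and all 9 central HOX genes (median 3.90) were higher, among them HOXA3 at 25.0 against 0.364 CPM, HOXC4 at 43.3 against 1.08 and HOXC5 at 15.0 against 0.100. Of 7 WNT targets 4 were higher (1.42), with LEF1 at 62.0 against 8.22 CPM and AXIN2, a feedback inhibitor of WNT signaling, at 29.8 against 4.80. Of 6 sclerotome and cartilage genes 4 were higher (1.64), with COL11A1 at 144 against 21.5 CPM and COL2A1 at 235 against 75.3. Of 9 cell cycle exit genes 7 were higher (1.37), with the CDK inhibitor CDKN1C at 176 against 20.9 CPM. Of 16 glycolysis genes 7 were higher (1.00), with LDHA at 368 against 32.3 CPM and ENO1 at 2019 against 432, and of 10 dissociation and immediate early genes 7 were higher and 1 lower (1.25), with FOS at 85.6 against 14.7 CPM.

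Neural lists went both ways. Of 8 neural progenitor genes 3 were higher and 1 lower (median 0.83), with PAX6 at 30.5 against 3.55 CPM and the forebrain gene LHX2 at 0.0820 against 17.6. Of 11 neuron genes 7 were lower and 1 higher (-1.72), with STMN2, a tubulin-binding protein of axons, at 14.1 against 85.6 CPM. Cluster 1, with 26.0% of the undifferentiated and 0.0151% of the day 8 cells, had neuron as its leading list (6 of 19 markers). Of 6 neural crest and Schwann cell genes 3 were higher and 2 lower (1.18), with TFAP2B at 20.5 against 2.02 CPM. Of 11 epithelium genes 5 were lower and 2 higher (-0.72), with the cadherin CDH1 at 29.5 against 163 CPM and the basal regulator TP63 at 27.1 against 0.774. These 12 lists stood apart from matched random lists. The muscle progenitor list did not (median 0.26, 2 of 9 higher, 1 lower), with PAX3 at a log2 ratio of 2.44 and the secreted inhibitor DLK1 at -4.65.

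The 11 other lists with enough members stayed among the random lists. Their medians were 0.59 for fibroblast and mesenchyme, 0.47 for BMP targets, 0.34 for hypoxia and integrated stress, 0.31 for the Notch pathway and 0.28 for cell cycle, of which 3 members were lower and 0 higher. The IGF and HGF axis had 0.18, smooth muscle and pericyte 0.05, extracellular matrix 0.03, FGF targets 0.03, primitive streak and presomitic mesoderm -0.21 and nuclear oxidative phosphorylation -0.46. The all-gene median was -0.05 and lay at 0.07 under TMM factors. The log2 ratio of COL3A1 of -1.52 and that of IGFBP4 of -1.86 depended on which undifferentiated cells were summed and lay at 1.12 and 0.06 without clusters 4 and 11.

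The comparison of day 12 with day 8 covers the phase in IGF1 alone, after FGF2, HGF and LDN193189 were withdrawn. Most measured feedback inhibitors and targets of FGF signaling were lower at day 12, and most BMP targets higher. The receptor signaling inhibitor SPRY2 stood at 7.37 against 54.1 CPM (log2 ratio -2.88, -2.96 to -2.80), SPRY1 at 26.3 against 168 (-2.67), the ERK phosphatase DUSP6 at 17.0 against 103 (-2.60) and the transcription factor ETV5 at 13.2 against 88.9 (-2.76). In contrast, the BMP-responsive homeobox gene MSX1 stood at 28.1 against 2.84 CPM (3.31) and ID2, an inhibitor of basic helix-loop-helix factors, at 271 against 63.8 (2.09). ISG15, an interferon-stimulated ubiquitin-like protein, had the highest ratio of the named genes, at 499 against 19.6 CPM (4.67, 4.62 to 4.72).

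Of 9652 genes measured, 376 were at least 2-fold higher and 67 at least 2-fold lower, a share of 84.9% higher, against 69.7% with TMM factors and 72.1% with DESeq2 size factors. The all-gene median of 0.07 lay at -0.14 and -0.12 under those scalings. Other genes with the largest ratios were the neural adhesion molecule CHL1 (4.28), ISG12(A) (3.14), THSD7A (3.0985), the MHC light chain B2M (2.99), the antiviral GTPase MX1 (2.83), the neuregulin receptor ERBB4 (2.64), TUBB3 (2.51) and IFI6 (2.49). On the lower side were SKAP1 (-3.24), the protease ADAM12 (-2.76), the phosphatase DUSP4 (-2.49), ITGA8 (-2.21), GREB1 (-1.68) and PHC2 (-1.59).

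By list, 9 of 11 FGF targets were lower and 0 higher (median -2.60), and 7 of 9 BMP targets higher and 0 lower (1.17). Of 12 neuron genes 8 were higher (1.84), with the neurofilament NEFL at 13.8 against 0.978 CPM and the synaptic protein SYT1 at 24.2 against 5.63. Of 8 neural progenitor genes 4 were higher (0.94), with DBX2 at 25.9 against 6.18 CPM and the fatty acid binding protein FABP7 at 61.5 against 17.3. Primitive streak and presomitic mesoderm held 2 higher and 1 lower of 4 (1.15), with the WNT agonist RSPO3 at 47.4 against 6.35 CPM and CDX4 at 9.47 against 28.6. The Notch pathway held 1 higher of 7 (0.66), fibroblast and mesenchyme 2 of 6 (0.45), with COL3A1 at 45.3 against 10.2 CPM, and extracellular matrix 3 of 15 (0.29), with fibronectin FN1 at 329 against 156 CPM. Epithelium stood apart at 0.27 with all 11 members within 2-fold. Glycolysis lay lower (-0.37, 1 of 16 lower), with LDHA at 169 against 368 CPM, and so did hypoxia and integrated stress (-0.34, 0 of 9 apart). The sclerotome and cartilage list stood apart at -0.19, yet 1 of its 6 members was higher and 0 lower, and its median had the other sign with filters at 1 or 50 CPM.

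Muscle progenitor genes did not stand apart (median 0.30, 2 of 8 higher, 1 lower), with EYA2, a transcriptional cofactor, at a log2 ratio of 1.54 and PAX7 at 1.35. The remaining medians were 0.38 for smooth muscle and pericyte, 0.31 for neural crest and Schwann cell, -0.00 for cell cycle, -0.00 for oxidative phosphorylation, -0.08 for immediate early genes, -0.09 for anterior HOX and -0.11 for pluripotent stem cell genes. Medians with the other sign under TMM factors were those of cell cycle exit (0.16 and -0.04), the IGF and HGF axis (0.14 and -0.06), WNT targets (0.08 and -0.13) and central HOX (0.08 and -0.13). The log2 ratio of SOX2 of 0.15 also had the other sign under both scalings.

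The comparison of day 20 with day 12 covers the return of HGF beside IGF1. Most measured epithelial genes were higher at day 20 and most cell cycle genes lower, and the medians of the neural progenitor and neuron lists were lower. KRT7, a keratin of simple epithelia, stood at 187 against 17.9 CPM (log2 ratio 3.38, 3.33 to 3.43), the epithelial laminin LAMA3 at 60.7 against 5.30 (3.52) and the claudin CLDN4 at 193 against 50.7 (1.93). SOX2 stood at 54.1 against 193 CPM (-1.84, -1.87 to -1.80). The mitotic regulator CDC20 stood at 28.3 against 94.1 CPM (-1.73) and the cyclin CCNB2 at 15.6 against 46.0 (-1.56). EYA4, a transcriptional cofactor in muscle progenitors, stood at 44.8 against 3.01 CPM (3.90, 3.77 to 4.02), while PAX7 stood at 10.3 against 34.8 (-1.76).

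Of 9984 genes measured, 560 were at least 2-fold higher and 717 at least 2-fold lower, a share of 43.9% higher, against 57.0% with TMM factors and 57.8% with DESeq2 size factors. The all-gene median of -0.15 lay at -0.01 and -0.00 under those scalings. Other genes with the largest ratios were the metallothionein MT1A (4.55), the secretory disulfide isomerase AGR2 (4.17), CCN3 (3.92), the protease inhibitor CST6 (3.51), the calcium-binding S100A12 (3.44) and S100A6 (3.25), CEMIP (3.28) and the transcription factor NFIB (3.19). On the lower side were the heparan sulfate enzyme HS3ST4 (84.7 against 916 CPM, -3.44), GUCY1A2 (-2.58), the transcription factor ZBTB16 (-2.51), ABTB3 (-2.50), TMEFF2 (-2.42), the axonal DPYSL5 (-2.32), the channel ASIC2 (-2.32), CNMD (-2.23), RNF220 (-2.23) and FRMD5 (-2.20).

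By list, 10 of 11 epithelium genes were higher and 0 lower (median 1.41), with WNT6 at 192 against 45.9 CPM and TP63 at 93.6 against 28.5. Of 6 contractile skeletal muscle genes 4 were higher (1.40), with SMPX at 110 against 12.9 CPM and TNNT1, a slow troponin, at 64.4 against 26.1. The list has 26 genes in the file, and the others lay below 10 CPM in both libraries. Among those, MYH3 stood at 0.725 against 0.914 CPM and MYH8 at 0.378 against 0.156. Sub-clusters 6 and 8, described below as carrying muscle markers, were 0.0291% of the day 20 cells. The fetal muscle stage list held 3 higher of 4 (1.93), with NFIA at 175 against 46.7 CPM. Of 9 fibroblast and mesenchyme genes 4 were higher (0.68), with the matrix protein POSTN at 29.9 against 3.74 CPM and the limb mesenchyme regulator PRRX1 at 21.2 against 5.15. Neural crest and Schwann cell genes held 3 higher and 1 lower of 6 (1.02, but -0.2328 with a filter at 1 CPM), with TFAP2A at 59.9 against 18.4 CPM, and trophoblast genes 1 higher of 5 (0.90), namely KRT7. The IGF and HGF axis held 5 higher of 11 (0.37), among them the HGF receptor MET at 12.1 against 2.92 CPM and the IGF-binding IGFBP3 at 105 against 13.9. BMP targets held 2 higher of 9 (0.33), with BAMBI at 29.4 against 10.8 CPM. Hypoxia and integrated stress genes held 6 higher of 11 (1.2017), with VEGFA at 21.5 against 5.77 CPM, and immediate early genes 8 of 12 (1.31), with FOS at 227 against 74.9. Glycolysis stood apart at 0.33, although 1 of 16 members, PFKM, was lower and 0 were higher.

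The lists on the lower side were cell cycle with 13 of 18 members lower (-1.26), neural progenitor with 5 lower and 1 higher of 9 (-1.16), and neuron with 5 lower of 12 (-0.87). FABP7, at 292 against 61.5 CPM, went against its list, and GAP43, a growth cone protein, stood at 30.009 against 100.04. All 5 anterior HOX genes were lower (-1.23), as were 4 of 11 central HOX genes (-0.89), with HOXC6 at 20.0 against 64.5 CPM. Of 6 sclerotome and cartilage genes 3 were lower (-0.72), with COL2A1 at 64.1 against 213 CPM. Muscle progenitor genes did not stand apart (0.16, 2 of 9 higher, 1 lower). The other medians were 0.22 for FGF targets, 0.17 for oxidative phosphorylation, 0.13 for WNT targets, 0.11 for smooth muscle and pericyte, -0.43 for the Notch pathway and -0.69 for primitive streak and presomitic mesoderm. Cell cycle exit genes had -0.19 with 2 of 9 higher, and extracellular matrix had -0.04, with 0.08 under TMM factors, and held 3 higher and 2 lower of 15.

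The comparison of day 25 with day 20 asks what the last days of IGF1 and HGF added. Most measured contractile muscle, tendon and neuron genes were higher at day 25, as were the basal keratins KRT5, KRT15 and KRT17. Among them, ACTC1 stood at 121 against 27.7 CPM (log2 ratio 2.12, 2.07 to 2.17), the atrial and embryonic light chain MYL4 at 10.5 against 0.552 (4.25), the slow troponin TNNI1 at 11.9 against 1.22 (3.30) and the thin filament gene NEB at 10.9 against 1.28 (3.09). TNMD, a membrane protein of tendon, stood at 34.4 against 5.18 CPM (2.73, 2.62 to 2.85). The basal keratin KRT15 stood at 95.2 against 1.78 CPM (5.74, 5.55 to 5.93) and KRT5 at 53.6 against 1.31 (5.36). DCX, a microtubule protein of young neurons, stood at 38.9 against 9.34 CPM (2.06).

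Of 10179 genes measured, 689 were at least 2-fold higher and 110 at least 2-fold lower, a share of 86.2% higher, against 74.8% with TMM factors and 72.6% with DESeq2 size factors. The all-gene median of 0.14 lay at 0.00 and -0.02 under those scalings. Other genes with the largest ratios were KRT17 (3.55), MT1A (3.14), the mineralization inhibitor MGP (2.93), RELN (2.72), the mechanosensitive channel PIEZO2 (2.66), ZNF804B (2.55), SLC7A4 (2.54) and ADAM12 (2.50). On the lower side were CHGB, a protein of secretory granules (-2.18), the zinc transporter SLC39A10 (-1.89), HS3ST4 (-1.66), the endoplasmic reticulum chaperone HSPA5 (-1.54), GBP1 (-1.50), GFPT1 (-1.43), GALNT3 (-1.40), the vesicle coat gene SEC23A (-1.31), SNAPC1 (-1.27) and COL2A1 (-1.27).

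By list, contractile skeletal muscle genes held 6 higher and 2 lower of 10 (median 1.14). ACTA1 was 1 of those lower, with a log2 ratio of -1.28 in the whole culture. Muscle progenitor genes held 3 higher and 0 lower of 10 (0.61), with the membrane protein CHODL at 34.7 against 13.8 CPM and PAX7 at a log2 ratio of 0.81. At day 25, PAX7 lay mostly outside sub-clusters 6 and 8, described below as carrying muscle markers. They held 8.522% of PAX7 UMIs in 2.562% of the cells. Tendon genes held 3 higher of 4 (1.54), with COL12A1 at 164 against 68.6 CPM, and fibroblast and mesenchyme genes 6 of 13 (0.98), with PRRX1 at 86.4 against 21.2. Neuron genes held 7 higher of 12 (1.27), with STMN2 at 134 against 33.4 CPM, and neural progenitor genes 3 of 8 (0.63), with the Notch target HES5 at 14.1 against 2.12 and ZIC1 at 36.6 against 14.6. Primitive streak and presomitic mesoderm genes held 4 higher of 5 (1.30), namely WNT3A, RSPO3, CYP26A1 and DLL3, which also act outside that tissue. WNT targets held 3 higher of 7 (0.75), with NKD1 at 61.5 against 16.0 CPM, epithelium 1 of 12 (0.32) and immediate early genes 4 of 12 (0.64).

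Lists that stood apart on the lower side were sclerotome and cartilage with 2 of 5 lower (-0.56), endoderm with 1 lower and 1 higher of 4 (-0.48) and cell cycle exit with all 10 within 2-fold (-0.21). The median and the members apart differed in sign for cell cycle (-0.24, 4 of 18 higher and 0 lower), where the replication genes MCM5 and PCNA had log2 ratios of 1.56 and 1.18, and for FGF targets (-0.24, 1 of 9 higher and 0 lower). Endoderm held the transport protein TTR at 13.7 against 0.869 CPM and AFP at 8.39 against 19.1. The other medians were 0.60 for anterior HOX, 0.54 for the Notch pathway, 0.50 for somite and dermomyotome, 0.43 for BMP targets, 0.33 for trophoblast, 0.31 for extracellular matrix and 0.29 for smooth muscle and pericyte. The IGF and HGF axis had 0.24, neural crest and Schwann cell 0.10 with -0.02 under TMM factors, oxidative phosphorylation -0.01, central HOX -0.06 with 2 of 11 higher, hypoxia and integrated stress -0.10 and glycolysis -0.19. SOX2, at a log2 ratio of 0.11, had the other sign under both scalings.

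The comparison of day 25 with undifferentiated cells spans the whole protocol. Most measured pluripotency genes were lower at day 25, and most contractile muscle, fibroblast and epithelium genes were higher in these libraries. The stem cell Ras gene ERAS stood at 0.233 against 69.7 CPM (log2 ratio -8.23, -8.77 to -7.73) and NANOG at 0.120 against 22.7 (-7.56). The fast troponin TNNI2 stood at 16.3 against 0.164 CPM (6.63, 5.97 to 7.39), POSTN at 111 against 1.31 (6.40), MSX1 at 113 against 0.783 (7.17) and TP63 at 102 against 0.774 (7.04). MYOD1 had a log2 ratio of 5.14 (4.15 to 6.37) and MYH3 4.67 (4.20 to 5.17).

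Of 10646 genes measured, 2083 were at least 2-fold higher and 1325 at least 2-fold lower, a share of 61.1% higher, against 55.2% with TMM factors (1874 and 1519) and 52.7% with DESeq2 size factors (1801 and 1618). The all-gene median of 0.02 lay at -0.12 under DESeq2 size factors. S100A12 stood at 217 CPM at day 25 with 0 UMIs before differentiation, and its log2 ratio was at least 12.96. CHI3L1 (60.1 CPM) and the heart and extraembryonic regulator HAND1 (58.5 CPM) each had 0.0182 CPM before differentiation, with intervals of the log2 ratio of 9.83 to 14.73 and 9.80 to 14.70. Other genes with the largest ratios were PLET1 (11.49), KRT15 (11.35), KRT5 (10.94, 9.39 to 13.22), SLC7A4 (9.09), MGP (8.85), WNT6 (8.27) and the defensin DEFB1 (9.19). On the lower side were TMEM132D (-7.68), the channel KCNG3 (-7.50), TNFSF11 (-7.29), LEFTY2 (-7.11), DNMT3B (-6.54), NXPH2 (-5.49), the histone H2AX (-5.38), PTCHD4 (-5.31) and TLL2 (-5.29).

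By list, contractile skeletal muscle genes held 8 higher and 1 lower of 10 (median 2.99), fetal muscle stage 3 higher of 4 (2.37), somite and dermomyotome 3 of 4 (3.43) and muscle progenitor 7 higher and 2 lower of 12 (1.78), with EYA4 at 75.8 against 9.83 CPM and SPRY1 at 22.4 against 113. Tendon held 4 higher and 1 lower of 5 (4.31), fibroblast and mesenchyme 12 higher of 14 (3.0995), extracellular matrix 9 higher and 1 lower of 17 (1.34), trophoblast 4 higher and 1 lower of 6 (2.86) and epithelium 7 higher and 2 lower of 12 (1.54). Neural progenitor held 4 higher and 1 lower of 8 (1.02), neural crest and Schwann cell 4 higher of 6 (1.62), anterior HOX 4 higher of 5 (4.15) and central HOX all 11 (3.38). WNT targets held 6 higher of 7 (2.83), BMP targets 9 higher and 1 lower of 10 (2.74), the IGF and HGF axis 6 higher of 11 (1.55) and cell cycle exit 8 of 10 (1.63). Glycolysis held 7 higher of 16 (0.68), hypoxia and integrated stress 8 higher and 1 lower of 13 (1.55) and immediate early genes 10 higher and 1 lower of 12 (2.44), with FOS at 509 against 14.7 CPM.

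The lists on the lower side were pluripotent stem cell with 7 of 9 lower (-6.32), FGF targets with 10 lower and 1 higher of 11 (-2.17), cell cycle with 15 of 19 lower (-1.32) and endoderm with 2 lower and 1 higher of 4 (-1.54). SPRY2 stood at 6.15 against 140 CPM and the cyclin CCNB1 at 19.2 against 124. The endoderm median had the other sign with doublets kept or with a filter at 1 CPM. The lists that did not stand apart were smooth muscle and pericyte (1.1957), sclerotome and cartilage (1.04), primitive streak and presomitic mesoderm (0.94), the Notch pathway (0.70), neuron (0.23) and oxidative phosphorylation (-0.51). In none of the 5 comparisons did the myoblast and myocyte, endothelium, cardiac muscle, intermediate mesoderm and kidney, blood and immune or posterior HOX list reach 4 measured members.

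**Figure D2:**
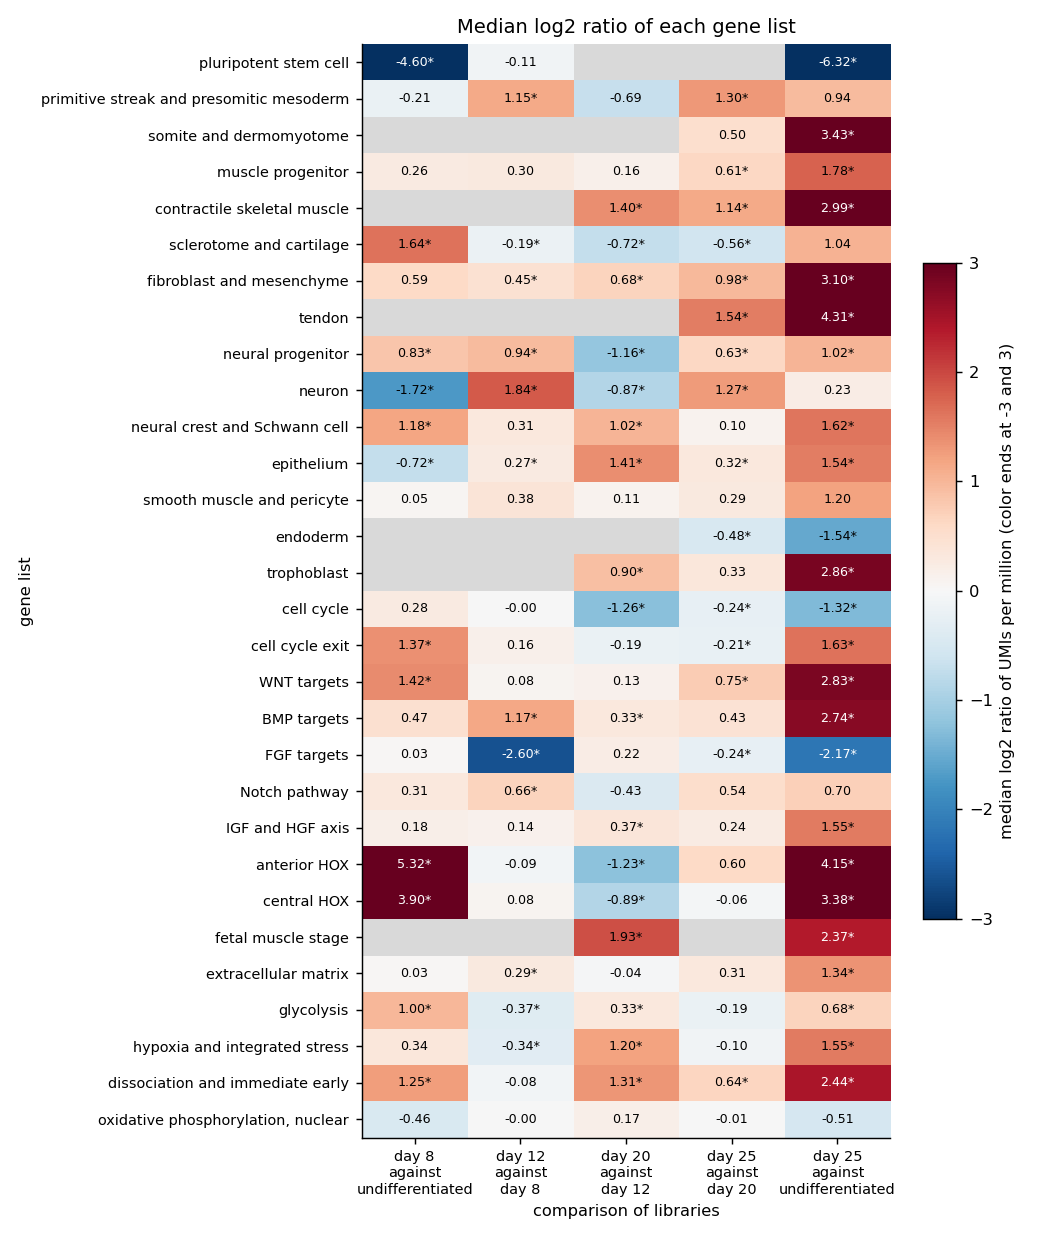
Median log2 ratio of CPM for each list in the 5 comparisons, with an asterisk where a list stood apart from 10000 matched random lists and grey where fewer than 4 members were measured; lists never reaching 4 members are not drawn. FGF targets lie at -2.60 at day 12 against day 8, and the contractile skeletal muscle list at 1.40, 1.14 and 2.99 where it was measured.

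Muscle genes were then followed cell by cell. After thinning to 2000 UMIs, 3 or more muscle progenitor genes were found in 2.24% of cells (Clopper-Pearson 95% interval 1.99 to 2.50) before differentiation, 0.987% (0.847 to 1.14) at day 8, 1.26% (1.11 to 1.43) at day 12, 3.03% (2.79 to 3.30) at day 20 and 4.35% (4.03 to 4.69) at day 25. In simulated droplets of free RNA the shares were 0.590%, 0.395%, 0.505%, 0.670% and 0.815%, and without thinning the cells gave 7.82%, 15.1%, 12.7%, 9.97% and 17.5%. Before differentiation, cluster 1 held 94.2% of PAX7, 92.5% of PAX3 and 69.0% of EYA1 UMIs. Its leading list was neuron (6 of 19 markers), followed by muscle progenitor (4 of 20). MYF5, MYOD1 and MYOG had 13, 8 and 0 UMIs in that library, and its share was not read as muscle progenitors. For contractile skeletal muscle genes the thinned shares were 0.103%, 0.0908%, 0.104%, 0.485% (0.388 to 0.599) and 1.59% (1.40 to 1.80), and the unthinned shares 3.18%, 3.39%, 3.91%, 4.88% and 9.99%. The free RNA droplets gave 0.275%, 0.120%, 0.175%, 1.25% and 5.20%, above the cells in every library. The contractile share of a whole library was therefore not read as expression. It was not read as a lack of expression either, since the simulated droplets held free RNA alone. In other cell types at day 25, 3 or more muscle progenitor genes were found in 2.81% of neuron-like cluster 14 and 0.169% of epithelium-like cluster 25, at median depths of 6342 and 10070 UMIs before thinning. The depth limit did not leave out cells evenly. Cluster 9 had contractile skeletal muscle as its leading list, with 5 of 26 markers. Of its 2040 day 25 cells, 338 entered these shares.

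**Figure D3:**
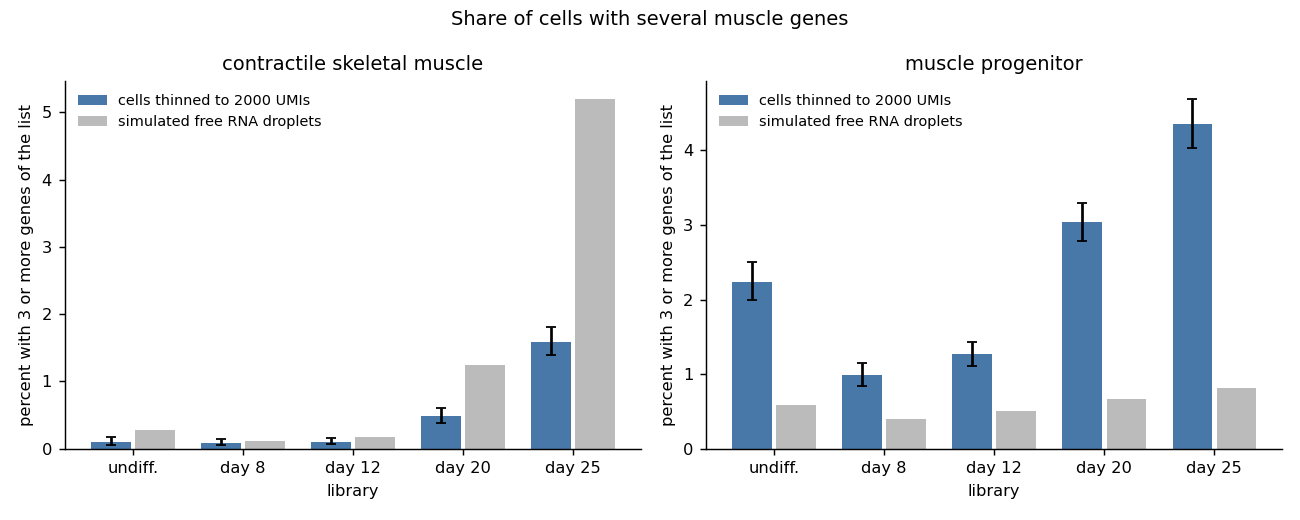
Percent of cells with 3 or more genes of the contractile skeletal muscle list and of the muscle progenitor list, thinned to 2000 UMIs, with 95% counting intervals, beside simulated droplets of free RNA. The muscle progenitor share of 4.35% at day 25 lies above its free RNA value of 0.815%, and the contractile share of 1.59% lies below its value of 5.20%.

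Clustering placed most clusters mainly in 1 library. Clusters 0, 2 and 3 were named pluripotent stem cell-like, 14 neuron-like, 22 and 23 neural progenitor-like, 25 and 26 epithelium-like and 20 fibroblast and mesenchyme-like, and all others stayed unnamed. No cluster was named skeletal muscle-like, which follows from the naming rule and sets no limit on the number of muscle cells. Cluster 20, at 15.8% of the day 25 cells, carried 12 of 26 contractile and 13 of 19 fibroblast markers. Cluster 19, at 8.12% of the day 20 cells, carried 7 of 20 muscle progenitor and 10 of 19 fibroblast markers and stayed unnamed by a rule set after seeing the data; it held 0.00534%, 0.829%, 0.810% and 0.180% of the undifferentiated, day 8, day 12 and day 25 libraries.

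Most UMIs of MYOD1 and MYF5 lay in those clusters, in cluster 20 at day 25 and in cluster 19 at day 20. Shares of MYOG and ACTC1 are given for day 25 only. At day 25 cluster 20 held 75.3% of MYOD1 UMIs, 71.4% of MYOG, 78.3% of MYF5 and 70.4% of ACTC1. At day 20 cluster 19 held 73.9% of MYOD1 and 69.8% of MYF5 UMIs. Further clustering of clusters 19 and 20 set apart sub-cluster 8, with 68 cells of day 25 and 1 of day 20, defined by 25 of 26 contractile markers, and sub-cluster 6, with 373 cells of day 25 and 5 of day 20, which carried 12 of 20 muscle progenitor, 7 of 16 myoblast and myocyte, 8 of 26 contractile and 8 of 19 fibroblast markers. Its top 10 genes held 1 muscle progenitor, 2 myoblast and myocyte and 2 contractile markers. Together they were 2.56% (2.33 to 2.81) of the day 25 cells and 0.0291% of the day 20 cells. The levels that follow describe the sub-clusters and test nothing, since such genes set them apart. In sub-cluster 8 MYOD1 stood at 253 CPM, MYOG at 157 and PAX3 at 59.8, with 0 UMIs of PAX7. In sub-cluster 6 PAX3 stood at 202 CPM, PAX7 at 73.4, MYF5 at 23.6, MYOD1 at 44.5 and MYOG at 11.8. Sub-cluster 5, with 1158 of its 1248 cells from day 20, held PAX3 at 263 CPM, EYA1 at 554 and MYOD1 at 10.8. It also held COL1A1 at 631 CPM, with MYOG at 0.337. It carried 10 of 19 fibroblast, 7 of 20 muscle progenitor and 0 of 16 myoblast and myocyte markers, so its class stays open.

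Single cells with MYOD1 at day 25 (63 after thinning) also had ACTC1 in 69.8% of cases (57.0 to 80.8), CDH15, a cadherin of satellite cells, in 23.8% and the acetylcholine receptor gene CHRNA1 in 22.2%, against 7.32%, 0.876% and 0.310% of cells without MYOD1. In simulated free RNA droplets of that library ACTC1 was found in 22.9%, CDH15 in 0.895%, CHRNA1 in 0.270% and MYOD1 itself in 0.335%, against MYOD1 in 0.423% of cells. CDH15 and CHRNA1 were chosen after their values were seen.

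**Figure D4:**
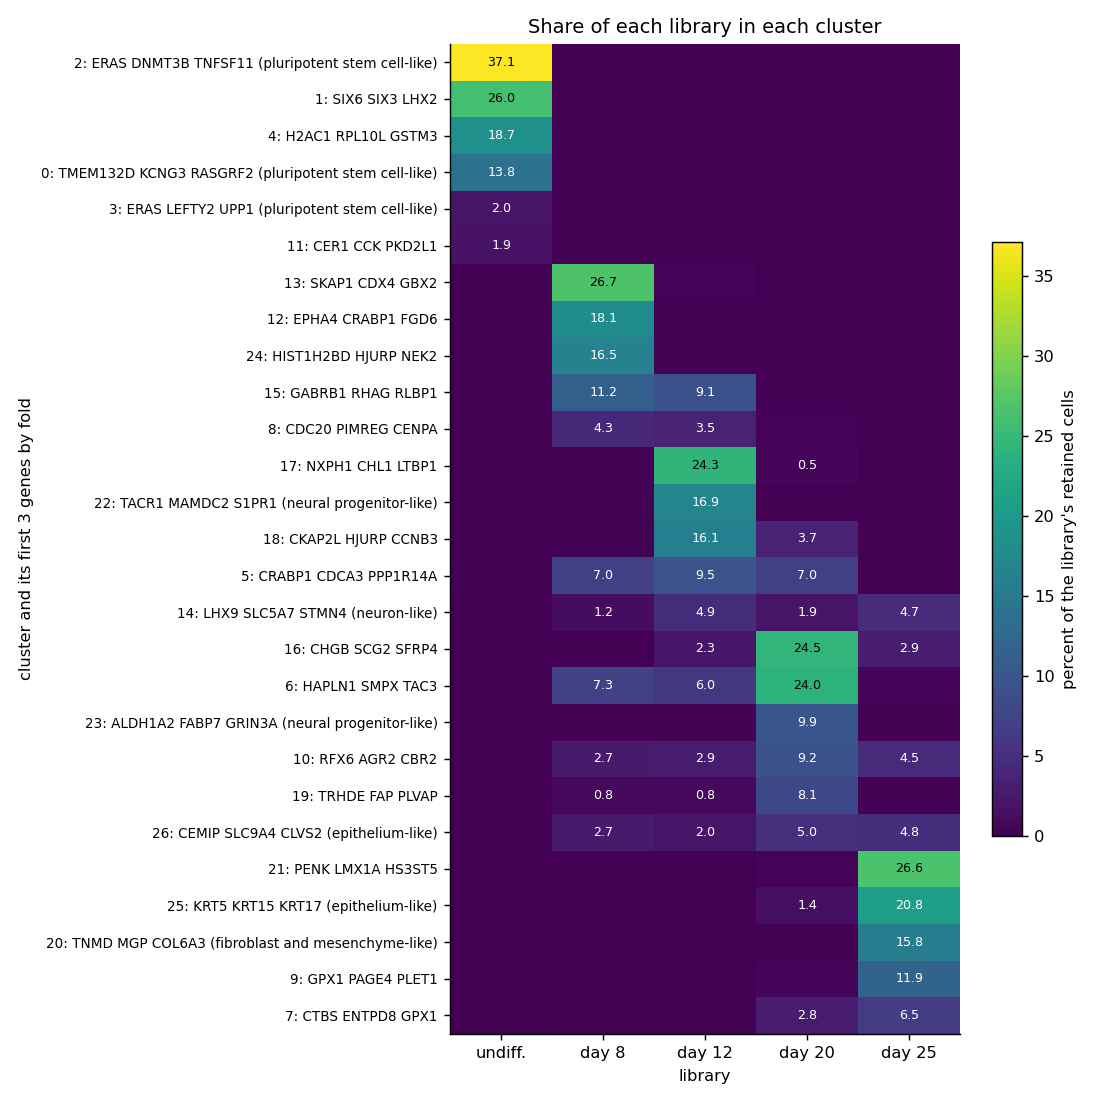
Percent of each library's retained cells in each cluster labelled by its first 3 genes by fold, with class names where given and values printed from 0.5% up. Most clusters lie in 1 library, such as cluster 2 with 37.1% of the undifferentiated cells and cluster 20 with 15.8% of the day 25 cells.

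Interferon-stimulated genes were collected in a list of 42 after the data were seen. Its median log2 ratio was 2.54 at day 12 against day 8, with 23 of 26 measured members higher and 0 lower, and 0.11 at day 8 against undifferentiated. It was 0.42 at day 20 against day 12 (8 of 30 higher) and 0.55 at day 25 against day 20 (10 of 36 higher, 1 lower). IFI44L stood at 0.510, 4.36, 49.6, 56.0 and 75.6 CPM in the order of the libraries. HERC5, the ligase for ISG15, went against the list before differentiation, at 233 CPM against 11.6 at day 8.

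**Figure D5:**
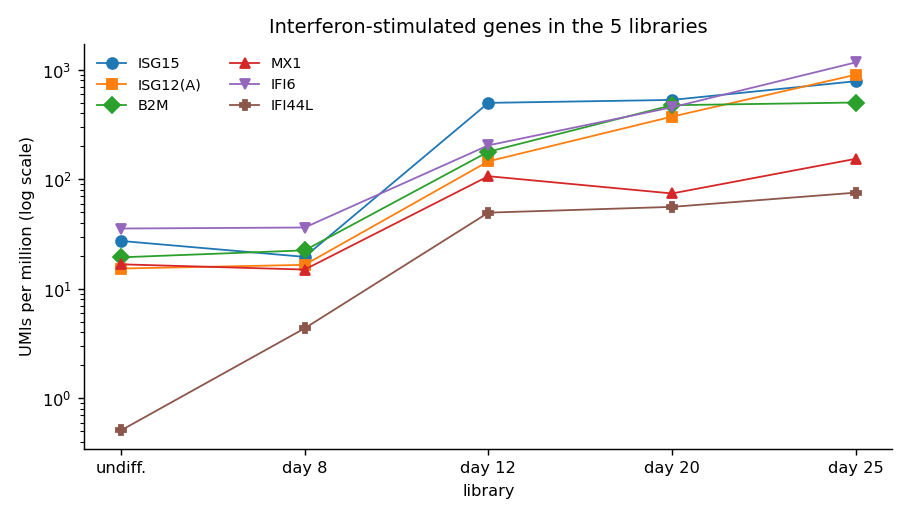
Levels of 6 interferon-stimulated genes in the 5 libraries, as CPM on a log axis, with 1 point per library. ISG15 lies at 27.4 and 19.6 before day 12 and at 499, 531 and 787 from day 12 on.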

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

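Chosen after the results were seen were the tests of PAX7 by cluster, by named neural clusters and by sub-clusters 6 and 8, the test of the genes higher in cluster 4 and the averaging over draws in the doublet test. RNA was also counted in barcodes outside the called cells, which the main comparisons do not use. The deposited files held all barcodes, those with free RNA included, so a count above 0 was certain beforehand and is no finding. The barcodes outside the called cells held 16.02% of all UMIs in the undifferentiated library (24256129 UMIs). They held 10.81% at day 8, 11.82% at day 12, 14.33% at day 20 and 15.67% at day 25.

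PAX7 at day 25 lay mostly outside sub-clusters 6 and 8 and went with SOX2. After thinning, SOX2 was found in 20.9% of cells with PAX7 (17.5 to 24.6) and 9.70% of cells without it, against 6.32% of free RNA droplets. Free RNA spread evenly was argued against by a 64.43-fold range of PAX7 between cluster 16 (59.2 CPM) and cluster 10 (0.919 CPM). Sub-clusters 6 and 8 held 8.522% of PAX7 UMIs in 2.562% of the cells, so they were not its main source. Muscle progenitors elsewhere were not covered, such as any in sub-cluster 7, which carried 7 of 20 muscle progenitor markers. The clusters named neural held 7.037% in 4.955% of the cells. Unnamed cluster 21 held 65.2% in 26.6% of the cells. Its leading lists were neural progenitor and neuron, tied at 4 of 19 markers with 0 in its top 10 genes, and its identity stayed open. Doublets of muscle and neural cells stay open, since the expected share with PAX7 and SOX2 in called doublets was 0.7672 times that in retained cells (0.322 to 1.57). Among 100 single thinning draws that ratio ran from 0.183 to 1.66, and the expectation over draws replaced a single draw after 2 draws had been seen to differ.

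Cluster 4 held 18.7% of the undifferentiated cells at a median of 1529 UMIs, with its own genes such as H2AC1 and GSTM3. For cells of another species, 0% of 365 genes abundant in all other clusters were over 8-fold lower in cluster 4. Each of 25 other clusters also gave 0%. This cannot decide the question, since free RNA can supply such abundant genes and no control of another species was at hand. Its correlation with free RNA was 0.9057, between the bounds set for and against droplets of free RNA, against 0.9444 to 0.9824 for clusters 0 to 3. The 626 genes higher in cluster 4 stood at a median of 3.369 times their free RNA level, which argues against droplets holding free RNA alone. The leading marker list of cluster 4 was fibroblast and mesenchyme, with 5 of 19 markers and 0 of them in its top 10 genes. COL1A1 stood at 328 CPM there against 11.1 to 21.1 in clusters 0 to 3. Cluster 4 held 55.8% of that library's COL1A1 UMIs, and its median mitochondrial share was 0.575%. No biological explanation was tested, and damaged cells may remain among the open ones.

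Interferon-stimulated genes were higher at day 12 than at day 8, with ISG15 at 499 against 19.6 CPM. Within 7 clusters present in both libraries, the median of the cluster medians of the log2 ratio was 1.621. The lowest cluster median was 0.769 and the highest 2.81. For those clusters this argued against a shift in cell composition as the whole cause. They left out the largest clusters of each day, such as 13 with 26.7% of day 8 and 17 with 24.3% of day 12 cells. Among the 7, clusters 5 and 15 had median depths of 0.196 and 0.277 of their library's median. Free RNA weighs more in such cells. Free RNA from a few producing cells stays open. The free RNA level was 1.048 times the cell level over 26 members. That cell level is summed over all cells, so few producers could also give a value near 1. The day of differentiation, with its change of medium, could be a source and stays untested, as does a difference between the single cultures.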

How the results depend on the processing

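Settings chosen after the results were seen were the sums without clusters 4 and 11 or without clusters of low depth and the 4 other countings of muscle-like cells. No paired analysis was possible because each group held 1 library. Under all settings together, 242 of 310 counts and shares stayed within their limits and 68 moved. Of 1512 list medians 1114 stayed, 393 moved and 5 reversed, and of 9072 gene ratios 7206 stayed, 1862 moved and 4 reversed. Reversed means that the sign turned for a list that stood apart or a gene at least 2-fold apart. Counting every sign, however near 0 the value, 48 list medians and 51 gene ratios had the other sign, of which 12 and 23 did so under TMM or DESeq2 factors.

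Filters at other levels measured more or fewer genes, which moves counts by construction. At 1 CPM, genes at least 2-fold higher and lower numbered 2027 and 2411 for day 8 against undifferentiated (20 lists apart), 937 and 128 for day 12 against day 8, 1142 and 1238 for day 20 against day 12 and 1410 and 314 for day 25 against day 20, with 3531 higher for day 25 against undifferentiated. At 50 CPM they numbered 452 and 660, 93 and 22 (7 lists apart), 217 and 249 (10 lists), 209 and 46 (8 lists) and 773 and 721 (11 lists). With TMM factors, day 12 against day 8 held 244 higher and 106 lower and day 25 against day 20 held 173 lower, which was 186 with DESeq2 size factors, and the cause was not tested.

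Of lists standing apart and genes at least 2-fold apart, 9 values reversed, and the cause was not tested. For day 8 against undifferentiated, COL3A1 (-1.52) had 0.0116 with filters at 1000 genes and 10% mitochondrial UMIs and 1.12 (1.1173) without clusters 4 and 11, where IGFBP4 (-1.86) had 0.0573. For day 12 against day 8, MYH8 (1.03) had -0.1213 with each cell weighted equally, and the sclerotome and cartilage list (-0.19) had 0.1699 at 1 CPM and 0.284 at 50 CPM. For day 20 against day 12, the neural crest and Schwann cell list (1.02) had -0.2328 at 1 CPM. For day 25 against undifferentiated, the endoderm list (-1.54) had 0.7878 with doublets kept and 0.0673 at 1 CPM.

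Shares of cells moved with depth and with the number of genes asked for, by construction. In the order undifferentiated, day 8, day 12, day 20 and day 25, muscle progenitor shares were 0.5864%, 0.2373%, 0.3432%, 1.266% and 1.412% at 1000 UMIs per cell. They were 10.25%, 7.926%, 7.198%, 8.236% and 12.76% at 2 or more genes and 0.02213%, 0.01135%, 0.05969%, 0.2764% and 0.5031% at 5 or more genes. Contractile shares were 0.02277%, 0.01515%, 0.0044%, 0.1717% and 1.056% at 1000 UMIs per cell, 2.324%, 1.254%, 1.527%, 4.62% and 6.607% at 2 or more genes and 0%, 0%, 0.004974%, 0.01692% and 0.6238% at 5 or more genes. Day 25 held the highest share under each of these settings. For the contractile list that ranking was not read as expression or as its absence, since its main shares lay below those of droplets holding free RNA alone.

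By the naming rule, the share of skeletal muscle-like cells was 0% in the main clustering and under each clustering setting fixed beforehand and depended on which cells were counted. Counting cluster 19 gave 0.8287% at day 8, 0.8096% at day 12, 8.122% at day 20 and 0.1801% at day 25. At days 20 and 25, counting sub-clusters 6 and 8 gave 0.02909% and 2.562%, cluster 20 0.1939% and 15.81%, and cluster 9, a cluster of low depth, 0.4703% and 11.85%.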

Other observations

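Genes for these paragraphs were chosen after their values were seen, except those the naming rule gives, and no test beyond those above was run. Before differentiation, PAX7 and PAX3 lay mostly in cluster 1, with 94.2% and 92.5% of their UMIs at 96.1 and 39.8 CPM. That cluster held 26.0% of the cells and was led by the eye and forebrain regulators SIX6, SIX3 and LHX2. Cluster 11, with 1.86% of the cells, was led by the Nodal and BMP antagonist CER1 and the peptide hormone CCK.

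At day 20, cells with PAX3 also had EYA1, a cofactor of myogenic transcription, in 21.998% of cases, against 4.28% of cells without PAX3 and 5.81% of free RNA droplets. At day 8, SOX2 was found in 28.4% of cells with PAX7 and 28.9% of those without it, against 22.2% of free RNA droplets.

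Sub-cluster 0, with 161 of its 205 cells from day 8, carried 7 of 16 somite and dermomyotome and 8 of 14 endothelium markers, among them MEOX1, TCF15 and PLVAP.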
